A study of Mus musculus with 11 samples.

How the data were processed

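Gene expression was measured on 11 Affymetrix whole-transcript mouse gene arrays of classical dendritic cells (cDCs) sorted from mouse spleen. Cells were sorted by flow cytometry, per the submitters' design text. Per the labels' protocols, spleens of C57BL/6 mice were digested with collagenase B and DNase I, total RNA was isolated with an RNAqueous-Micro kit, and targets were amplified with the Ovation PicoSL kit and labelled with biotin. The groups were CD24+ cDCs of control mice (3 arrays), CD172a+ cDCs of control mice (4 arrays) and CD172a+ cDCs of mice with floxed Zeb2 and a CD11c-Cre transgene (4 arrays). Control mice carried floxed Zeb2 without Cre, per the labels. Each array's group and replicate number came from its title. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical.

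The values are log2 expression values per probe set as deposited, made with RMA per the submitters' processing notes. RMA subtracts background, applies quantile normalization between arrays and summarises the probes of a probe set, which shrinks differences near background. The software version, the probe filters and the genome build were not given in the sources used here, so no coordinates are printed. Array medians of the log2 values lay between 5.454 and 5.521. The number of arrays limits the precision, with 8 residual degrees of freedom in the fit. No pair of arrays had identical values at more than 5.2% of probe sets, and all arrays were counted as separate samples.

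Probe sets were named through the platform annotation. Of 30177 probe sets, 21789 carried 1 gene symbol, 1621 carried several and 6767 carried none. Of the probe sets with 1 gene, 21698 matched the RefSeq gene table of the GRCm38.p6 assembly by Entrez identifier, and 0 symbols had to be updated. Each of 19938 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for 999 genes with more than 1 probe set. Probe sets with several genes or none were left out of the gene-level tests and tested separately by probe set. Ly6c2, a gene fixed for naming, was measured by a probe set shared with other genes and was not analysed here.

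Group means were compared with limma 3.58.1 in R 4.3.3, with 1 linear model over all 11 arrays and group as the only factor, moderated variances and Benjamini-Hochberg adjustment over all 19938 genes. All tests were two-sided at an adjusted p threshold of 0.05. The 3 comparisons were CD172a+ cDCs labelled Zeb2-deficient against control CD172a+ cDCs, control CD24+ against control CD172a+ cDCs, and CD172a+ cDCs labelled Zeb2-deficient against control CD24+ cDCs. Standard errors are those of limma. Single values and list means were compared by exact permutation of the array labels. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and tables were handled with pandas 2.3.3 and numpy 2.4.6.

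The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The 26 lists covered markers of cDC1, cDC2, plasmacytoid DCs (pDCs), monocytes, splenic macrophages, B cells, T cells, NK cells, neutrophils, and erythroid cells and platelets. They also covered DC transcription factors, the Notch pathway, TGF-beta, BMP and SMAD signalling, epithelial genes repressed by Zeb factors, MHC class II, MHC class I, Toll-like receptors, C-type lectin receptors, interferon-stimulated genes, chemokines and their receptors, DC maturation, cell cycle, immediate-early genes induced by dissociation, cytokine and growth factor receptors, ribosomal proteins and mitochondrial respiration. Of 620 memberships, 570 were measured. Lists were tested with camera in limma, which compares a list with all other genes, with a preset correlation of 0.01 and adjustment over the 26 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way, were run beside it.

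Genes were named by rule. In each of the first 2 comparisons the rule took up to 12 genes with the largest change in each direction among those past the threshold whose groups did not overlap, and in the third comparison 5 in each direction. It left out predicted genes, clone names, microRNAs, small nucleolar RNAs, olfactory and vomeronasal receptors, and immunoglobulin and T cell receptor segments. It added up to 4 members with the smallest p of each list described and a fixed set of dendritic cell genes. Genes named outside the rule are said to be so.

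Replicate numbers were checked as a possible pairing. Deviations from the group means of same-numbered control and labelled Zeb2-deficient CD172a+ arrays correlated across genes at r from 0.442 to 0.68 in 4 pairs, all above the 0.1 taken as a hint of pairing. This hint came from the data and not from the labels. Other-numbered pairs of the same array set gave 0.496 to 0.699, pairs from different array sets gave -0.692 to -0.404, and same-numbered CD24+ and CD172a+ arrays gave -0.445 to 0.592. The correlations thus followed the array set, and the replicate number itself was not shown to pair the arrays. The first principal component of the within-group deviations separated 2 array sets that cross all 3 groups. The first set held replicate 1 of the CD24+ cDCs and replicates 1 and 2 of both CD172a+ groups (5 arrays), and the second held the other 6 arrays. The array set was used as a block in the fit and as a split of the arrays, an alternative chosen after seeing the data.

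Other alternatives were fits of only the groups compared, the replicate number as a block, array weights, a variance trend with robust moderation, quantile normalization again, arrays shifted to 1 median, filters at the 25th and 50th percentile of mean expression, the mean of all probe sets of a gene, every probe set by itself, a test against a minimum fold of 1.5 (treat), and leaving out each array in turn. The procedure was tested on simulated data built from the real means and spreads of 19938 genes, with 200 genes changed per run in 10 runs. In the simulated comparison of 4 labelled Zeb2-deficient with 4 control arrays, it recovered 43.3% of genes changed 1.5-fold, 78.2% of genes changed 2-fold and 97.6% of genes changed 4-fold, and 5.69% of calls were false. For control CD24+ against CD172a+ cDCs, the shares recovered were 35.7%, 74.2% and 96.1% at the same folds, and 5.84% of calls were false. These simulations drew the arrays independently. With the 2 array sets simulated as well, the fit with group as the only factor recovered 36.3%, 74.6% and 96.4% for labelled Zeb2-deficient against control CD172a+ cDCs, with 0.648% of calls false, and the fit with the array set as a block recovered 63%, 90.7% and 99.8%, with 5.48% false. For control CD24+ against CD172a+ cDCs the shares were 29.7%, 69% and 95% without the block (0.923% false) and 55.7%, 88.7% and 99.8% with it (4.63% false).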

Results

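The data describe the genes expressed by the main classical dendritic cell subsets of mouse spleen and by CD172a+ cDCs of mice designed to lack Zeb2, a zinc-finger transcriptional repressor, in cells expressing CD11c. CD24+ cDCs correspond to the cDC1 subset and CD172a+ cDCs to the cDC2 subset. The arrays comprised 3 of control CD24+ cDCs, 4 of control CD172a+ cDCs and 4 of CD172a+ cDCs labelled Zeb2-deficient. Over all genes, the first principal component held 39.9% of the variance and separated CD24+ from CD172a+ cDCs. The second component held 34.2% and separated the 2 array sets that cross the groups. Of the genes tested, 5998 differed between the array sets with adjusted p below 0.05 in limma, 2798 being higher and 3200 lower in the second set, a count that only describes the sets because they were found from the same values. Splenic macrophage markers were among those higher in the second set, with 16 of 19 measured members higher and 1 lower. Immediate-early genes induced by dissociation were lower there in 16 of 19. Because every group spans both array sets, differences between groups are given over all arrays, and for the main counts, the leading genes and the lists past the threshold also with the array set as a block (chosen after seeing the data) or within each set. The CD24+ group holds 1 array in the first set and 2 in the second.

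**Figure D1:**
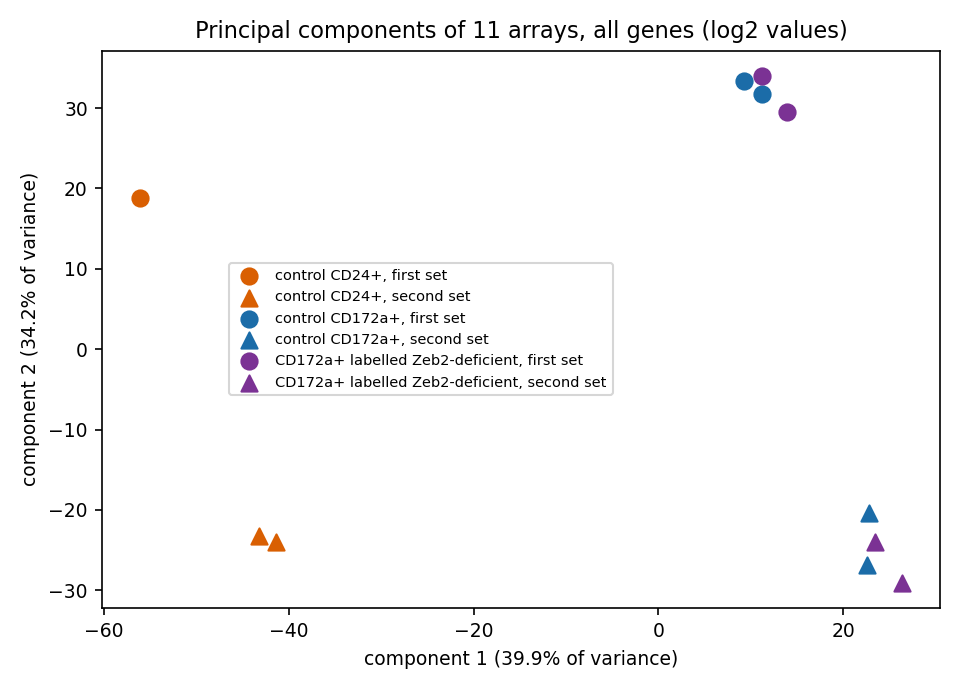
The 11 arrays are plotted on the first (horizontal, 39.9% of variance) and second (vertical, 34.2%) principal components of the log2 values of all genes, with colour for group and shape for array set. CD24+ arrays lie apart from CD172a+ arrays along the first component, while control and labelled Zeb2-deficient CD172a+ arrays of a set lie close together.

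Zeb2 was measured first as a check of the labels, by probe set 10482448. In control CD172a+ cDCs the 4 arrays read 8.23, 8.23, 8.26 and 8.62, with a mean of 8.34 ± 0.19 (SD, n = 4). In CD172a+ cDCs labelled Zeb2-deficient they read 8.52, 8.32, 9.07 and 9.24, with a mean of 8.79 ± 0.44 (SD, n = 4). In control CD24+ cDCs they read 5.19, 5.08 and 5.52, with a mean of 5.26 ± 0.23 (SD, n = 3). Zeb2 in the arrays labelled Zeb2-deficient was thus not lower than in controls, and the difference of 0.45 did not pass the exact two-sided permutation test (p = 0.171, 70 assignments, smallest possible p 0.0286) or limma (adjusted p = 0.998). It was 0.19 in the first array set and 0.72 in the second. The antisense transcript Zeb2os differed by 0.23 (exact p = 0.343). Where the Zeb2 probe set lies relative to the deleted part of the gene is not given in the sources used here, so it checks little or nothing about the deletion, and the group is called labelled Zeb2-deficient throughout. Every direction given for this group rests on that label.

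The comparison of CD172a+ cDCs labelled Zeb2-deficient with control CD172a+ cDCs was made to find genes that depend on Zeb2 in this subset. Only the mice labelled Zeb2-deficient carried the CD11c-Cre transgene. An effect of the transgene itself therefore cannot be told apart from loss of Zeb2 for any difference of this group. Plcb4, a phospholipase C that cleaves membrane phosphoinositides downstream of G proteins, rose from 5.59 ± 0.25 to 8.25 ± 0.39 (SD, n = 4 each), a 6.28-fold difference (log2 2.65, SE 0.191). Itgad, the alpha chain of a beta-2 integrin known as CD11d, rose 4.90-fold, from 5.54 ± 0.36 to 7.83 ± 0.14. Cox6a2, the heart and muscle form of a cytochrome c oxidase subunit and a marker of pDCs, rose 4.27-fold, from 6.79 ± 0.23 to 8.88 ± 0.22. Fcer2a, the low-affinity IgE receptor CD23 best known from B cells, rose 4.14-fold, from 4.43 ± 0.06 to 6.48 ± 0.21. Lyz2, the lysozyme of myeloid cells, fell 3.15-fold, from 10.82 ± 0.23 to 9.17 ± 0.34, and Scn3a, a voltage-gated sodium channel subunit, fell 2.65-fold, from 6.38 ± 0.30 to 4.97 ± 0.27. Smaller rises were those of Eif2ak3, the PERK kinase of the unfolded protein response (2.20-fold), Plce1, another phospholipase C (2.07-fold), Slc27a2, a fatty acid transport protein (1.87-fold), and Gramd3 (1.77-fold). The lower means of Fcer2a, Plce1 and Scn3a lay under the median level of all genes (5.52 in control CD172a+ cDCs). RMA values shrink near background, so the folds of these genes are not exact ratios.

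These 10 genes, 8 higher and 2 lower, were the ones with adjusted p below 0.05 in limma, and 8 of them differed at least 2-fold. At an unadjusted p below 0.05 there were 773 genes, 3.88% of those tested. Adjusted p ranged from 4.74e-05 for Fcer2a to 0.0429 for Plce1, and the arrays of the 2 groups did not overlap for any of the 10. Chance gives this for 2.86% of unselected genes. Genes picked by small p on the same arrays nearly always show it, so it adds no support. All 10 also passed with the array set as a block, with adjusted p of 9.5e-08 for Plcb4, 6.11e-07 for Fcer2a, 2.57e-06 for Itgad, 2.53e-05 for Cox6a2 and 0.00213 for Lyz2. Within the first and second sets the differences were 2.52 and 2.78 for Plcb4, 2.41 and 2.17 for Itgad, 2.39 and 1.80 for Cox6a2, 1.93 and 2.17 for Fcer2a, and -1.36 and -1.96 for Lyz2. A second Itgad probe set differed by -0.01, and the near-identical Lyz1 differed by -1.93 (adjusted p = 0.998). The calls of 4 genes were lost when 1 array was left out, while their differences stayed of similar size. Eif2ak3 did not pass without control replicate 1, 2, 3 or 4 or without labelled Zeb2-deficient replicate 3 (adjusted p from 0.09 to 0.132), with differences of 1.13 to 1.16 against 1.14 over all arrays. Plce1 did not pass without any 1 of the 4 control replicates or without labelled Zeb2-deficient replicate 1, 3 or 4 (0.0917 to 0.174), with differences of 0.93 to 1.10 against 1.05. Gramd3 did not pass without control replicate 2 (0.0609) or labelled Zeb2-deficient replicate 1 (0.0517), with differences of 0.81 and 0.80 against 0.82. Scn3a did not pass without control replicate 3 (0.0528), with a difference of -1.43 against -1.41.

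**Figure D2:**
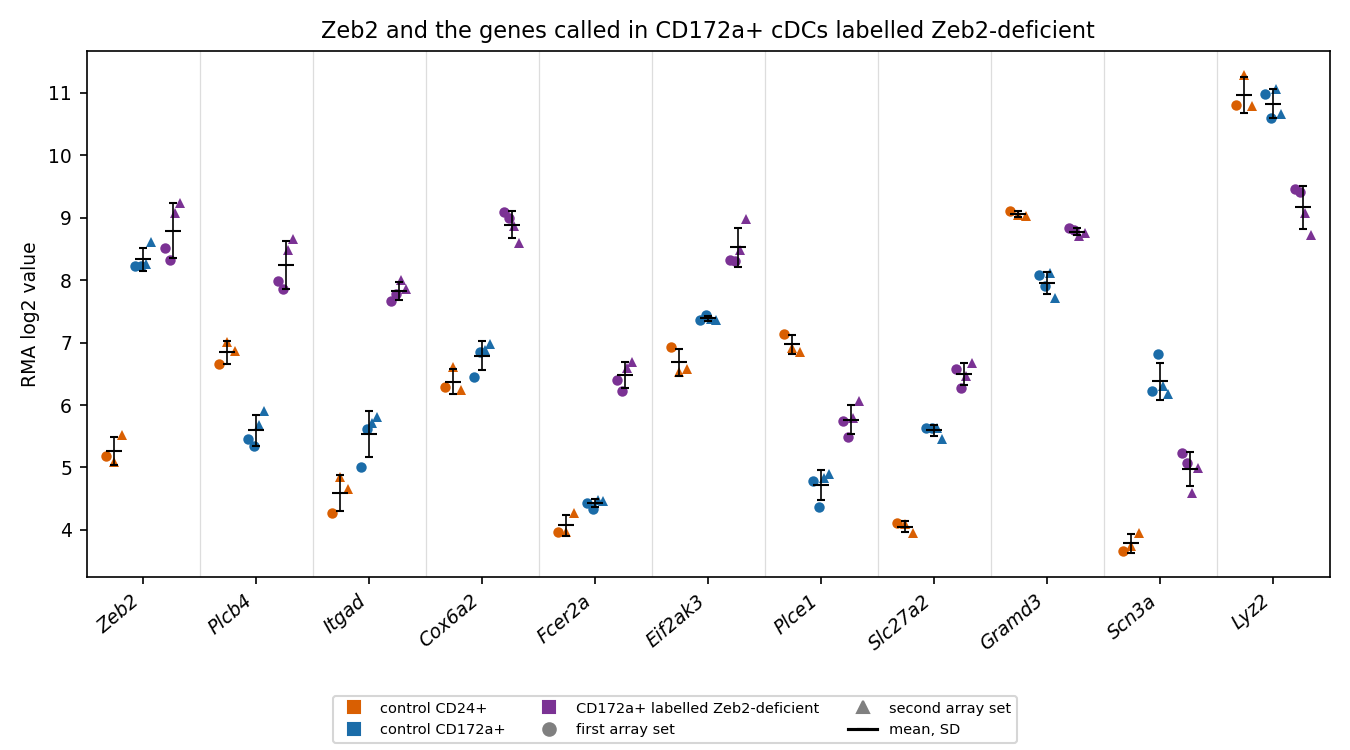
Log2 values of Zeb2 and of the 10 genes past the threshold in limma are plotted per array for the 3 groups, with shape for array set and bars for mean and SD (n = 3 for CD24+ and 4 for each CD172a+ group). Plcb4 averaged 8.25 in arrays labelled Zeb2-deficient and 5.59 in control CD172a+ arrays, while Zeb2 averaged 8.79 and 8.34.

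With the array set as a block, 29 genes passed, 18 higher and 11 lower, and with the replicate number as a block on the 8 CD172a+ arrays 26 passed, 20 higher and 6 lower. Both contained the 10 genes above, and 19 genes were shared between them. Within the first set 0 genes passed in limma (2260 at an unadjusted p below 0.05), and within the second 7 passed, of which 3 were among the 10 genes above. Ms4a1, the B cell surface protein CD20, read 8.22 ± 0.50 against 6.20 ± 0.56, a log2 difference of 2.02 with an adjusted p of 0.135 over all arrays and 0.00201 with the array set as a block. Csf1r, the receptor for the macrophage growth factor M-CSF, read 7.47 ± 0.34 against 8.42 ± 0.06, a difference of -0.94 with adjusted p of 0.129 and 0.0304. Epcam, an epithelial adhesion molecule, read 5.72 ± 0.29 against 4.75 ± 0.24, a difference of 0.96 with adjusted p of 0.152 and 0.00621, and 0.0419 with the replicate number as a block over all arrays.

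The genes that define cDC subsets did not pass this comparison. Irf4, a transcription factor of cDC2, differed by 0.35, Irf8, a factor of cDC1, by 0.05 and Batf3, another factor of cDC1, by 0.39. Id2, an inhibitor of E proteins that restrains pDC development, differed by 0.57 and Tcf4, the E protein that drives pDCs, by -0.27. Klf4 differed by 0.30, Notch2 by 0.03 and Zeb1, the paralog of Zeb2, by 0.02. Of surface markers, Sirpa, which encodes CD172a, differed by -0.18, Itgam by 0.34, Cd4 by -0.32, Esam by -0.36, Cd24a by 0.24, Cd8a by 0.02, Xcr1 by 0.22, Clec9a by -0.72 and the pDC receptor Siglech by 0.43. The adjusted p in limma was 0.998 for each of these 17 genes. Within the first and second sets the differences had opposite signs for Irf8 (0.41 and -0.30), Cd4 (0.13 and -0.77), Siglech (-0.04 and 0.91), Zeb1 (-0.11 and 0.14) and Cd8a (0.04 and -0.01), and for Clec9a they were -0.33 and -1.11. Runx1, chosen from the list of DC transcription factors, differed by -0.46 (adjusted p = 0.637), and 0 of the 39 measured members of that list passed.

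Monocyte markers were lower as a list (camera adjusted p = 0.000153), with 1 of 26 measured members lower, 0 higher and 25 not passed. Adjusted over the list alone, 4 were lower, namely Lyz2, Csf1r, Ccr2 (-1.23), a receptor that recruits monocytes, and Adgre4 (-1.20), a surface protein of the EGF-TM7 family. The list had an adjusted p = 0.0331 with an estimated correlation, and its median was -0.12, -0.13 in the first set and -0.17 in the second. B cell markers were higher as a list (camera adjusted p = 0.000227), with 1 of 14 measured members higher, 0 lower and 13 not passed. Adjusted over the list alone, 3 were higher, namely Fcer2a, Ms4a1 and Fcrla (0.41). The list had an adjusted p = 0.0331 with an estimated correlation, and its median was 0.11, 0.32 in the first set and 0.009 in the second. With the array set as a block both lists passed camera (0.000119 and 0.00254), with an adjusted p = 0.132 and 0.143 with an estimated correlation. By exact permutation of the list means each reached the smallest possible p of 0.0286, which adjusted over the 26 lists was 0.372.

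Cell cycle genes were lower as a list (camera adjusted p = 8.09e-10, median -0.37). The call was lost with adjusted p = 0.5 with an estimated correlation. None of its 24 measured members passed over all genes and 1, Nusap1 of the mitotic spindle (-0.62), was lower when adjusted over the list alone, while 23 of 24 had a negative difference, such as the proliferation marker Mki67 (-0.40) and the cyclin Ccna2 (-0.55). The medians within the sets were -0.35 and -0.33. The list also differed between array sets, with 15 of 24 members lower in the second. Interferon-stimulated genes were higher as a list (camera adjusted p = 0.00971, median 0.29), with 0 of 19 passed and 0 adjusted over the list alone. Their adjusted p = 0.811 with an estimated correlation, their medians were 0.43 and 0.11 within the sets, and 11 of the 19 were lower in the second array set. cDC1 markers were higher (camera adjusted p = 0.00971, median 0.15), with 0 of 27 passed and 0 adjusted over the list alone. For them adjusted p = 0.5 with an estimated correlation, and the medians within the sets were 0.22 and 0.09. Epithelial genes repressed by Zeb factors were higher (camera adjusted p = 0.00971, median 0.12), with 0 of 24 passed and 1, Epcam, adjusted over the list alone. For these adjusted p = 0.5 with an estimated correlation, with medians of 0.19 and 0.08 within the sets. The tight junction genes Crb3 (0.33) and Cldn1 (1.20) of this list did not pass. C-type lectin receptors were lower (camera adjusted p = 0.0231, median -0.11), with 0 of 27 passed and 0 adjusted over the list alone, adjusted p = 0.5 with an estimated correlation and medians of -0.18 and -0.17 within the sets. With 1 array left out, interferon-stimulated genes did not pass camera without control replicate 3 or 4 or labelled Zeb2-deficient replicate 1 or 2 (adjusted p from 0.0773 to 0.824). C-type lectin receptors did not pass without control replicate 4 or labelled Zeb2-deficient replicate 1 or 2 (0.0886 to 0.226), and cDC1 markers without control replicate 2 or labelled Zeb2-deficient replicate 1 or 4 (0.0513 to 0.0777). Epithelial genes did not pass without control replicate 1 or 2 or labelled Zeb2-deficient replicate 4 (0.0526 to 0.0609).

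The other 19 lists did not pass camera. Of pDC markers (camera adjusted p = 0.164, median 0.12), Cox6a2 was higher and 21 of 22 did not pass, with the same count adjusted over the list alone. Of cDC2 markers (camera adjusted p = 0.705, median -0.02), 0 of 29 passed and 1, Csf1r, was lower when adjusted over the list alone. NK cell markers had a median of 0.09 (camera adjusted p = 0.0658, and 0.0446 with the replicate number as a block, while adjusted p = 0.736 with an estimated correlation and no block), splenic macrophage markers -0.08 (0.779) and immediate-early genes 0.05 (0.975). Some lists passed when 1 array was left out, namely NK cell markers without control replicate 3 or labelled Zeb2-deficient replicate 1 or 2 (0.0119 to 0.0391) and pDC markers without control replicate 1 (0.0408) or labelled Zeb2-deficient replicate 3 (0.0306). Without control replicate 1 the macrophage markers (0.0464) and ribosomal proteins (0.0263) passed, without control replicate 3 mitochondrial respiration genes (0.00395), and without labelled Zeb2-deficient replicate 3 MHC class II genes (0.045).

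The comparison of control CD24+ with control CD172a+ cDCs gives the difference between the subsets. The chemokine receptor gene Xcr1 averaged 10.89 ± 0.25 in CD24+ cDCs (SD, n = 3) and 5.47 ± 0.42 in CD172a+ cDCs (SD, n = 4), a 42.8-fold difference. Clec9a, a receptor for dead cells, was 29.1-fold higher, Cd8a 21.8-fold, Tlr3, the receptor for double-stranded RNA, 17.4-fold and Itgae, which encodes CD103, 10.1-fold higher in CD24+ cDCs. Tlr7, the receptor for single-stranded RNA, was 35.3-fold lower in CD24+ cDCs (3.21 ± 0.04 against 8.35 ± 0.25), as were the inhibitory C-type lectin gene Clec4a4 (37.7-fold), Itgam, which encodes CD11b (16.7-fold), and Cd4 (10.1-fold). Of transcription factors, Zeb2 was 8.40-fold lower and Irf4 9.23-fold lower in CD24+ cDCs, while Irf8 was 8.38-fold (log2 3.07, and 2.44 without CD24+ replicate 1) and Id2 2.03-fold higher. Sirpa and Cd24a, whose products were used to sort the cells, were 26.3-fold lower and 5.29-fold higher in CD24+ cDCs and are no finding. RMA values shrink near background, and folds against a mean below the median level of all genes (5.52 in control CD172a+ cDCs), as for Xcr1, Itgae, Tlr7, Clec4a4, Itgam, Cd4 and Zeb2, are not exact ratios.

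In limma, 1278 genes passed, 648 higher and 630 lower in CD24+ cDCs, and 614 of them differed at least 2-fold. All 1278 had the same sign within both array sets, which is nearly fixed in advance, since they were picked over the same arrays. The sizes could differ between sets, as for Irf8 and Irf4 below, and the first set holds 1 CD24+ array. Within the second set 1753 genes passed, and 3080 passed with the array set as a block (1705 higher, 1375 lower). Groups did not overlap for 1271 of the 1278. Ordered by fitted difference, the rises named in CD24+ cDCs were those of Gpr141b (log2 6.43, SE 0.261), an orphan receptor gene, Ifi205 (6.26, SE 0.306), an interferon-inducible gene, Xcr1 (5.42, SE 0.226), P3h2 (5.14), Rab7b (5.12), the scavenger receptor gene Cd36 (4.96), Clec9a (4.86), P2ry14 (4.85), Hepacam2 (4.71), Cd8a (4.44), Naaa (4.40) and Plpp1 (4.18). The falls named in the same way were those of Clec4a4 (-5.24, SE 0.279), Tlr7 (-5.14, SE 0.151), Clec4a1 (-5.10), Sirpa (-4.72), Rtp4 (-4.62), Adgre1, a macrophage surface marker (-4.57), Dscam (-4.38), Mmp12, the macrophage elastase (-4.35), Sh2d1b1 (-4.20), Clec4a3 (-4.12), Ptgs2, the inducible cyclooxygenase (-4.07), and Itgam (-4.06). Adjusted p for these 24 genes ranged from 2.28e-08 to 0.000181. Except for Clec9a, Cd8a, Naaa, Sirpa and Ptgs2, the lower mean lay under the median level of all genes in its group, so these differences are not exact and their order is not a measured one. Clec4a1, Clec4a3 and Clec4a4, like Ifi205, have close relatives in the genome whose transcripts probe sets may share. Klf4 (-0.95), Tcf4 (-0.63), Csf1r (-2.71) and Esam (-1.03) were also lower in CD24+ cDCs. Esam did not pass without any 1 of the CD24+ replicates or without control CD172a+ replicate 1 or 2 (adjusted p from 0.0733 to 0.0913, differences of -1.05 to -0.88). Batf3 (0.33), Notch2 (0.21), Zeb1 (-0.02) and Siglech (-0.42) did not pass, although Batf3 and Notch2 had adjusted p of 0.0471 and 0.0418 with the array set as a block. Within the first and second sets the differences were -3.04 and -3.14 for Zeb2, 4.85 and 1.92 for Irf8, and -4.44 and -2.38 for Irf4, and without CD24+ replicate 1 Irf8 differed by 2.44 against 3.07 over all arrays.

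**Figure D3:**
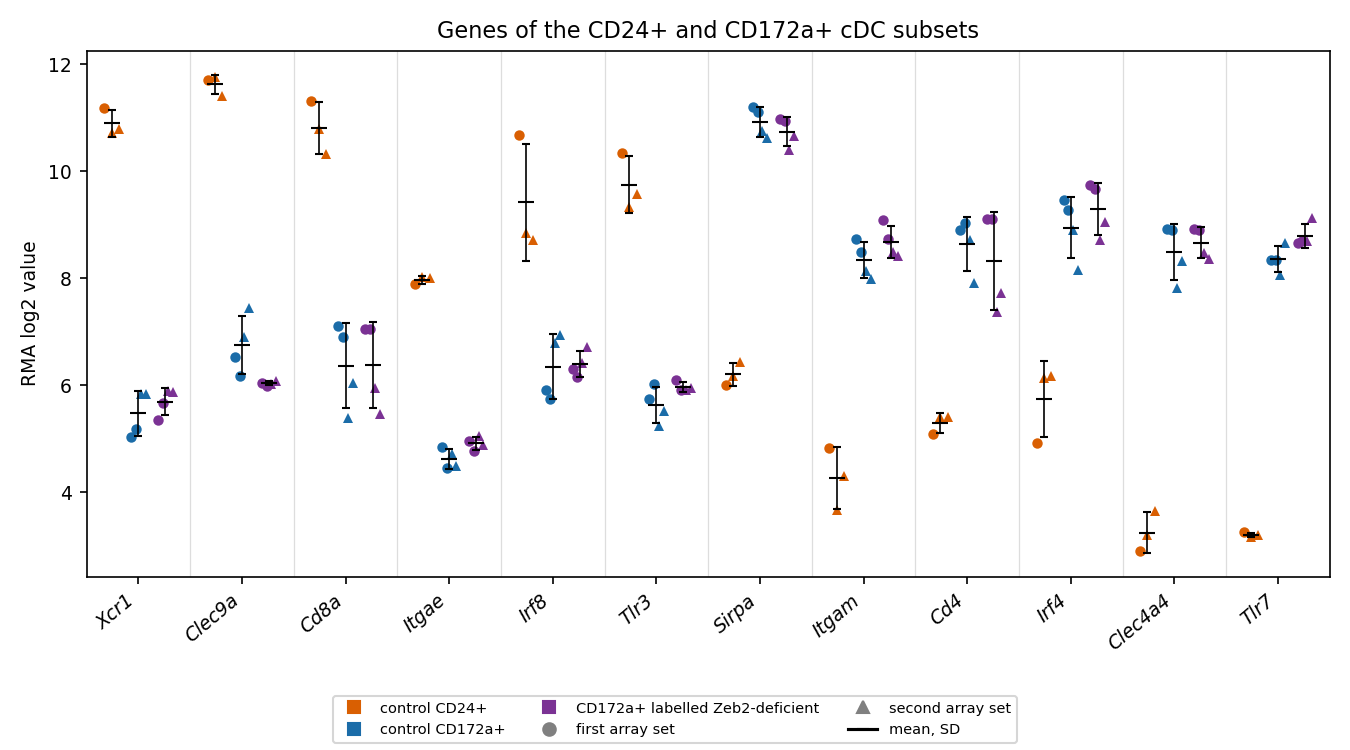
Log2 values of 12 genes of the cDC subsets are plotted per array for the 3 groups, with shape for array set and bars for mean and SD (n = 3 for CD24+ and 4 for each CD172a+ group). Xcr1 averaged 10.89 in CD24+ arrays, 5.47 in control CD172a+ arrays and 5.69 in arrays labelled Zeb2-deficient.

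Of the lists, cDC1 markers were higher in CD24+ cDCs in 25 of 27 measured members, with 0 lower and 26 higher when adjusted over the list alone (median 3.07, camera adjusted p = 7.91e-51). Of cDC2 markers, 20 of 29 were lower and 2 higher (23 and 2 adjusted over the list alone, median -2.26, camera adjusted p = 1.94e-25). The higher members were Clec12a (2.35), an inhibitory lectin receptor, named after its value was seen, and Rbpj (0.84), the transcription factor of Notch signalling, which did not pass without CD24+ replicate 2 (0.72, adjusted p = 0.0517). Monocyte markers were lower in 11 of 26 (12 lower and 2 higher adjusted over the list alone, camera adjusted p = 5.89e-08), such as Adgre1, Ms4a4c (-4.02) and Adgre4 (-3.28). MHC class I genes were higher in 4 of 14, and 8 adjusted over the list alone (median 0.66, camera adjusted p = 3.34e-07). They were the peptide-loading genes Pdia3 (1.19) and Canx (0.64), the transporter Tap2 (0.91) and the immunoproteasome gene Psmb8 (1.01), which did not pass without any 1 of the CD24+ replicates or without control CD172a+ replicate 1, 2 or 3 (adjusted p from 0.0511 to 0.146, differences of 0.965 to 1.12). These lists kept the call with adjusted p of 0.000802 for cDC1, 0.0038 for cDC2 and monocyte markers and 0.0388 for MHC class I with an estimated correlation. Cytokine and growth factor receptors were lower in 6 of 28, including Il1r2 (-3.08, and -2.28 without CD24+ replicate 1) and Csf3r (-0.71), with 9 lower and 3 higher adjusted over the list alone (camera adjusted p = 0.00161). Their adjusted p = 0.0388 with an estimated correlation became 0.0777 with the array set as a block. Within the first and second sets the medians were 3.24 and 2.69 for cDC1 markers, -3.04 and -1.70 for cDC2 markers, -0.41 and -0.65 for monocyte markers, 0.74 and 0.70 for MHC class I genes, and -0.39 and -0.29 for cytokine and growth factor receptors.

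Interferon-stimulated genes were lower in CD24+ cDCs in 9 of 19, such as Rtp4, Ifit3 (-3.80) and Ifit1 (-2.13), while Mx1, named after its value was seen, was higher (1.41), with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.9e-06). The call was lost with adjusted p = 0.319 with an estimated correlation. Of the fits with 1 array left out, Mx1 passed only in that without control CD172a+ replicate 2, and in the others it differed by 1.13 to 1.60 (adjusted p from 0.0517 to 0.133). Their median was -1.33 in the first set and -0.39 in the second, and 11 of the 19 were lower in the second array set, which holds 2 of the 3 CD24+ arrays. C-type lectin receptors were lower in 10 of 27 and higher in 4 (10 and 5 adjusted over the list alone, camera adjusted p = 0.000259), with adjusted p = 0.137 with an estimated correlation and medians of -0.34 and -0.75 within the sets. DC transcription factors were lower in 7 of 39, including Prdm1 (-1.77), and higher in 3 (9 and 4 adjusted over the list alone, camera adjusted p = 0.0304), with adjusted p = 0.109 with an estimated correlation and medians of -0.10 and -0.03 within the sets. Mitochondrial respiration genes were higher as a list (median 0.41, camera adjusted p = 4.64e-05), with 1 of 26 passed, the cytochrome gene Cyc1 (0.64, and 0.57 with adjusted p = 0.0688 without CD24+ replicate 3), also adjusted over the list alone. For this list adjusted p = 0.372 with an estimated correlation, and 0.0398 with an estimated correlation and the array set as a block, and the medians within the sets were 0.28 and 0.47. Cell cycle genes were lower as a list (median -0.22, camera adjusted p = 0.0435), with Nusap1 and Mki67 the 2 of 24 passed, also adjusted over the list alone, and adjusted p = 0.689 with an estimated correlation. Their median was -0.52 in the first set and 0.04 in the second, so that the direction turned between sets. Mki67 did not pass without CD24+ replicate 1 or 2 or control CD172a+ replicate 1, 2 or 4 (adjusted p from 0.0523 to 0.117, differences of -0.57 to -0.43). Immediate-early genes were lower as a list (median -0.34, camera adjusted p = 0.0296), with 0 of 19 passed and 0 adjusted over the list alone, and adjusted p = 0.689 with an estimated correlation. Their median was -0.40 in the first set, with 1 CD24+ array, and -0.02 in the second, and 16 of the 19 were lower in the second array set. With the array set as a block, cell cycle genes (0.225) and DC transcription factors (0.0644) no longer passed camera. Without CD24+ replicate 2 or control CD172a+ replicate 1 or 2, neither list passed (adjusted p from 0.0974 to 0.461 and from 0.0593 to 0.106). Immediate-early genes did not pass without CD24+ replicate 2 or 3 or control CD172a+ replicate 1 or 2 (0.0918 to 0.274).

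**Figure D4:**
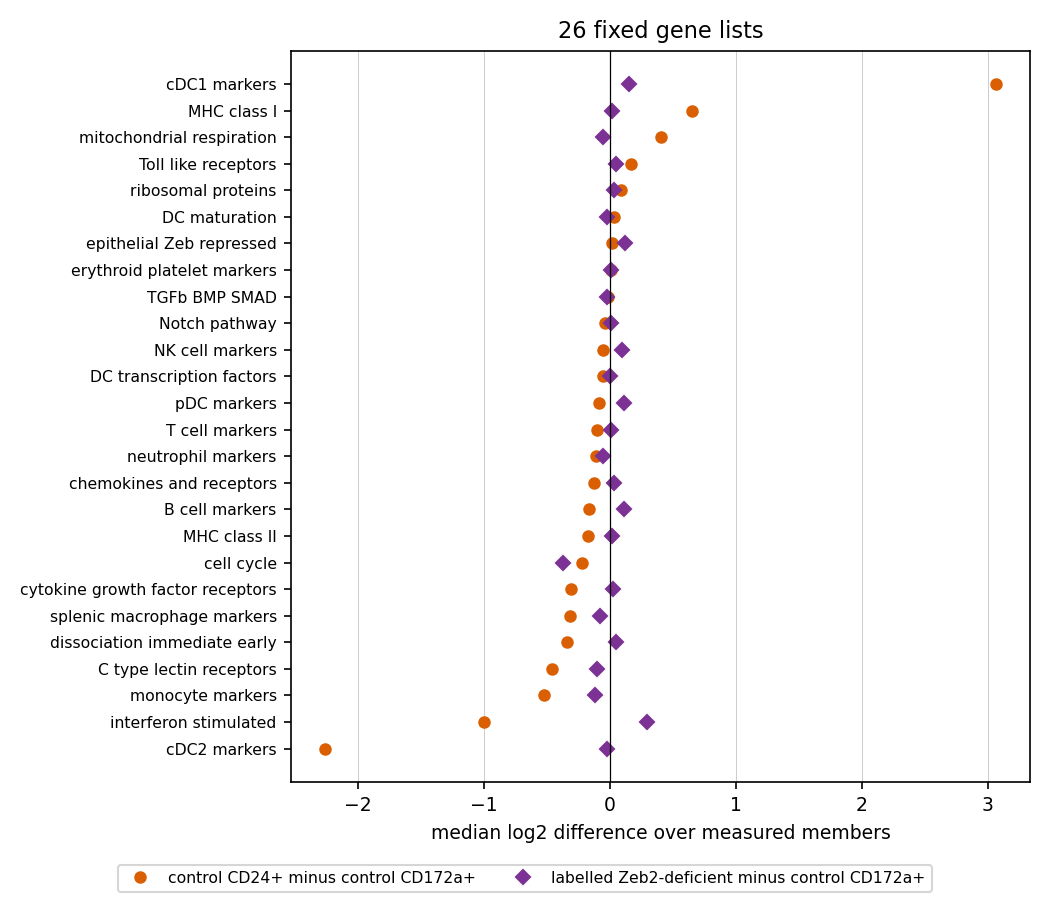
The median log2 difference over the measured members of each of the 26 gene lists is plotted for control CD24+ minus control CD172a+ cDCs (circles) and for labelled Zeb2-deficient minus control CD172a+ cDCs (diamonds). In the first, cDC1 markers lie at 3.07 and cDC2 markers at -2.26, and in the second at 0.15 and -0.02.

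CD172a+ cDCs labelled Zeb2-deficient were also compared with control CD24+ cDCs, with no gene list tested. Tlr7 was 47.9-fold higher in the CD172a+ cells (8.79 ± 0.23, n = 4, against 3.21 ± 0.04, n = 3, SD), Clec4a4 42.6-fold, Clec4a1 28.2-fold, Rtp4 26.5-fold and Sh2d1b1, an adaptor of SLAM receptors, 23.4-fold higher. Gpr141b was 89.5-fold lower (4.50 ± 0.52 against 10.98 ± 0.10), Clec9a 48.0-fold, Ifi205 47.3-fold, P2ry14, a receptor for nucleotide sugars, 39.6-fold and P3h2 37.2-fold lower. For Gpr141b, P2ry14 and P3h2 in the CD172a+ cells, and for Tlr7, Clec4a4, Clec4a1, Rtp4 and Sh2d1b1 in CD24+ cDCs, the lower mean lay under the median level of all genes, and these folds are not exact ratios. Zeb2 was higher by 3.52, Sirpa by 4.54 and Irf4 by 3.56, and Irf8 differed by -3.01 (-2.38 without CD24+ replicate 1) and Xcr1 by -5.20. In limma, 1429 genes passed, 647 higher and 782 lower in CD172a+ cDCs labelled Zeb2-deficient, and 663 differed at least 2-fold. All 1429 had the same sign within both array sets, which is again nearly fixed by picking them over the same arrays. Within the second set 1935 passed, and 3641 passed with the array set as a block (1500 higher, 2141 lower).

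Whether the genes that differ in CD172a+ cDCs labelled Zeb2-deficient are those that separate the subsets was asked across genes, which are not independent replicates. Plcb4, Plce1 and Gramd3 were higher both in the labelled Zeb2-deficient cells and in CD24+ cDCs, and Scn3a was lower in both. Itgad, Eif2ak3 and Slc27a2 were higher in the labelled Zeb2-deficient cells and lower in CD24+ cDCs. The difference in CD24+ cDCs did not pass for Itgad without CD24+ replicate 1 (-0.79, adjusted p = 0.0577) or for Eif2ak3 without CD24+ replicate 2 or 3 or control CD172a+ replicate 1 or 2 (-0.71 to -0.63, 0.0513 to 0.107). Independent lists of these sizes would share 0.26 genes higher in both, 0.0632 lower in both and 0.253 higher in the first and lower in the second. Unchanged groups simulated against the same control arrays shared 0.01 genes over all directions, but a group without effect has almost no calls to share, so this value does not bear on how lists of the observed sizes relate. The log2 differences of all 19938 genes from the shared control CD172a+ arrays had r = 0.118 and a covariance of 0.0095. The jackknife standard error of r over arrays was 0.123, larger than r itself, and without control CD172a+ replicate 4 r was 0.214. Simulated groups without any effect had r = 0.463 and a covariance of 0.0208, and the observed minus simulated covariance was -0.0113. With the array set as a block r was 0.106, against 0.458 simulated. The covariances were then 0.00862 observed and 0.00922 simulated, with a difference of -0.000594. The difference of -0.0113 thus depended on how the array sets were treated, and no conclusion is drawn from it. Within the first and second sets r was 0.167 and 0.175, values that still share controls. With the controls split so that each comparison had its own 2 arrays, 1 of each set, r lay between -0.0433 and 0.0165.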

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

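In groups of 4 arrays, 132 sets of values of named genes were tested for 1 array far from the other 3, by its gap to the nearest of them as a share of the group's range, and 5 passed Dixon's 95% critical value. Chance marks about 1 in 20 such groups. In control CD172a+ cDCs, replicate 4 stood apart for Zeb2, at 8.615 against 8.231 to 8.262 in the others, a share of 0.92. It also stood apart for Plpp1, at 4.709 against 4.229 to 4.274 (0.907), and for Slc27a2, at 5.461 against 5.64 in each of the others (a share of 1 after rounding). Replicate 2 of that group stood apart for Eif2ak3, at 7.448 against 7.363 to 7.37 (0.924). In CD172a+ cDCs labelled Zeb2-deficient, replicate 4 stood apart for Tlr7, at 9.131 against 8.653 to 8.691 (0.921). Without control replicate 4 the Zeb2 difference was 0.547, with Zeb2 higher in the arrays labelled Zeb2-deficient.

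Probe sets with several genes or none took part in no comparison of genes. Of 8388 such probe sets, 1 passed in limma between CD172a+ cDCs labelled Zeb2-deficient and control CD172a+ cDCs. It was probe set 10429564, which names no gene, and it was higher by 1.463 in the arrays labelled Zeb2-deficient (adjusted p = 0.00085), in 4 of 4 arrays. Its values were 8.10 to 8.51 there, 6.71 to 7.04 in control CD172a+ cDCs and 7.92 to 8.19 in control CD24+ cDCs.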

How the results depend on the processing

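The alternatives with the array set, the fits within a set and the replicate block on 8 arrays were chosen after seeing the data, and the other alternatives before the data were examined. Of 5615 values of named genes under alternatives, 5353 kept their side of the threshold, 173 no longer passed, 89 passed newly and 0 that passed reversed. Among the 5353 were 41 that passed in neither setting and had the other sign. For labelled Zeb2-deficient against control CD172a+ cDCs, 10 genes passed, against 5 when only these groups were fitted, 4 against a minimum fold of 1.5, 29 with the array set as a block and 0 within the first set (2260 at an unadjusted p below 0.05 in limma). By construction the minimum fold is stricter, and the fits of only these groups or of 1 set hold fewer arrays. In simulated data with array sets the block raised the share of genes recovered from 36.3% to 63% at 1.5-fold and from 74.6% to 90.7% at 2-fold, while 0.648% of calls were false without it and 5.48% with it. Plcb4, Itgad, Cox6a2 and Fcer2a passed in every setting run apart from the fits within a set, in 21, 21, 21 and 20 settings. Eif2ak3 passed in 14 of 21, Plce1 in 11 of 21, Gramd3 in 16 of 21, Scn3a in 17 of 20, Slc27a2 in 18 of 20 and Lyz2 in 20 of 21. Leaving out 1 array at a time gave 7 to 11 genes. For control CD24+ against CD172a+ cDCs, 1278 genes became 362 against a minimum fold of 1.5 and 3080 with the array set as a block, and 874 to 1140 with 1 array left out. For labelled Zeb2-deficient CD172a+ against CD24+ cDCs, 1429 became 342 and 3641, and 985 to 1226. Lists passing in the first comparison went from 7 to 2 with an estimated correlation, 2 in fry and 0 with the array set as a block and an estimated correlation, and those in the second from 11 to 5, 11 and 5. The 11 in fry held 8 of the 11 in camera, without cell cycle, immediate-early and mitochondrial respiration genes. Fry added Toll-like receptors (adjusted p = 0.00215), B cell markers (0.00834) and neutrophil markers (0.0466), all lower in CD24+ cDCs. For the lists the cause was not tested. With 1 array left out, 5 to 9 and 9 to 12 lists passed. The correlation of the differences went from 0.118 to -0.0946 as the mean of 6 splits of the controls and -0.0081 as the mean of 4 splits with both array sets on each side. By construction the splits remove the shared controls, but the 2 splits that part the controls by array set gave -0.281 and -0.254. These put the difference between the array sets into both comparisons. Only the mean of the 4 other splits therefore bears on the shared controls. The jackknife standard error of the correlation over arrays was 0.123. With 1 array left out the correlation lay between 0.0966 and 0.214, the highest without control CD172a+ replicate 4. The Zeb2 difference was 0.302 to 0.611 with 1 array left out. Signal near background limits what a fall can show, since a gene at that level cannot fall further.

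With the replicate number as a block, 26 genes passed on the 8 CD172a+ arrays, although the numbers were not shown to pair the arrays beyond the array set. Replicate 2 lies in the second set for CD24+ cDCs and in the first for both CD172a+ groups. Its deviations correlated at -0.445 with control and -0.361 with labelled Zeb2-deficient CD172a+ replicate 2. For comparisons with CD24+ cDCs, the block over all arrays thus conflicts with the array set, and no conclusion is drawn from its calls. With the block over all 11 arrays the counts were 11, 1843 and 2049 genes, 8 and 13 lists, a correlation of 0.128 and a Zeb2 difference of 0.453 (exact p = 0.125 from paired sign changes). With it NK cell markers passed camera in the first comparison (adjusted p = 0.0446) and B cell markers (0.0214) and MHC class II genes (0.0135) in the second, with no estimated correlation run for this block. Epcam (0.0419) passed newly in the first comparison, and in the second Cd68, Nr1h3, Klrk1, Fosb, Atf3 and Rpl14 did, while Mki67 no longer passed. The block over all arrays changed no other call of a named gene or list, and 4 of 11 arrays correlated best with their own number.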

Other observations

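The tests of a shared batch, with the array set as a block, with the replicate number on 8 arrays, on markers within each array set and on monocyte markers above the median level were chosen only after the results were seen. Between control CD24+ and CD172a+ cDCs, Toll-like receptor genes moved both ways. Tlr3 (4.12) and Tlr12 (1.98), a receptor for profilin, were higher in CD24+ cDCs, and Tlr7 (-5.14), Tlr1 (-3.31), Tlr6 (-0.90), Tlr2 (-0.62) and the adaptor gene Ticam2 (-1.78) were lower, 2 and 5 of 15 also adjusted over the list alone. Tlr2 did not pass without any 1 of the arrays except control CD172a+ replicate 2 (-0.68 to -0.51, adjusted p from 0.051 to 0.13), nor Ticam2 without CD24+ replicate 2 (-1.41, 0.0575). The list's median was 0.17 and its mean -0.34, with camera pointing down (adjusted p = 0.179). Of 30 chemokine and receptor genes, 6 were higher and 3 lower (8 and 5 adjusted over the list alone), with a median of -0.13, a mean of 0.20 and camera pointing up (adjusted p = 0.445). Xcr1, Ccl22 (2.15), Ccl17 (0.70), Ccl2 (1.63), Cxcr3 (2.19) and Ccr9 (2.03) were higher, and Ccl9 (-1.89), Ccr6 (-1.52) and Gpr183 (-1.91), an oxysterol receptor, were lower. Tlr6, Tlr2, Ticam2, Ccl22, Ccl17, Ccl2, Ccr6 and Gpr183 lie outside the naming rule and were chosen after their values were seen. Without CD24+ replicate 2 or 3 or control CD172a+ replicate 1 or 2, Ccl22 did not pass (1.81 to 2.01, adjusted p from 0.0904 to 0.151), and without these or control CD172a+ replicate 3 Ccl17 did not (0.61 to 0.74, 0.0582 to 0.166). Of 25 DC maturation genes, Il15 (1.63), Ccl22 and Ccl17 were higher and Cd274 (-1.99) and Pdcd1lg2 (-1.61), the ligands of PD-1, and Traf1 (-0.73) were lower (camera adjusted p = 0.851, and 0.0284 without CD24+ replicate 1, 5 and 3 adjusted over the list alone). Of 13 MHC class II genes, the protease genes Lgmn (-1.46) and Ctsl (-0.66) and the factor Rfx5 (-0.64) were lower (camera adjusted p = 0.1, and 0.00398 without control CD172a+ replicate 4, 3 adjusted over the list alone). Of the fits with 1 array left out, Ctsl passed only in that without control CD172a+ replicate 4, with -0.71 to -0.56 in the others (0.0675 to 0.133), and Rfx5 did not pass without CD24+ replicate 2 (-0.54, 0.0747) or 3 (-0.65, 0.0501).

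Further lists did not pass camera in this comparison. Notch pathway genes had 3 higher and 2 lower of 26, with a median of -0.04, a mean of -0.04 and camera pointing up (adjusted p = 0.886), the same counts adjusted over the list alone, and examples in Notch4 (0.89) and Maml3 (-1.16). TGF-beta, BMP and SMAD genes had 3 higher, such as Acvrl1 (1.08), and 1 lower, Smad4 (-0.60), of 30, with 3 and 2 adjusted over the list alone and camera pointing up (adjusted p = 0.955) although median and mean were -0.02 and -0.007. B cell markers had 1 higher and 3 lower of 14 (camera adjusted p = 0.0726), with Fcrla (0.93) higher and Cd22 (-2.36), Cd72 (-2.18) and Cr2 (-0.65) lower, and 1 and 5 adjusted over the list alone. Of pDC markers 1 was higher, Ccr9, and 4 lower of 22 (camera adjusted p = 0.281), and of NK cell markers Klrd1 (-2.91) and Tbx21 (-1.29) were lower of 14 (0.501). Epithelial genes had Cldn1 (2.37) and Marveld2 (0.72) higher and St14 (-1.37) lower of 24 (0.886). Neutrophil markers had Csf3r and Mmp9 (-0.93) lower of 14 (0.0726), and of 11 erythroid and platelet markers Itgb3 (-1.13) was lower (0.886), with a median of 0.01 and a mean of -0.07. With 1 array left out, Cldn1 differed by 3.13 without CD24+ replicate 1 and did not pass without replicate 2 (1.95, adjusted p = 0.0792) or 3 (2.05, 0.0827), and it differed by 1.05 in the first array set and 2.94 in the second. Marveld2 did not pass without CD24+ replicate 2 or 3 or control CD172a+ replicate 1, 2 or 4 (0.54 to 0.75, 0.0674 to 0.11), and Cr2 without CD24+ replicate 1 or 3 or control CD172a+ replicate 2 or 4 (-0.72 to -0.48, 0.0601 to 0.111). Tbx21 did not pass without any 1 of the CD24+ replicates or control CD172a+ replicate 3 or 4 (-1.45 to -1.08, 0.0667 to 0.155). Smad4 did not pass without CD24+ replicate 2 or control CD172a+ replicate 1 or 2 (-0.60 to -0.48, 0.0518 to 0.0975), and Mmp9 without CD24+ replicate 1 (-0.87, 0.0634) or 2 (-0.92, 0.0655). Splenic macrophage markers (median -0.32, 0.0726), T cell markers (-0.10, 0.189) and ribosomal proteins (0.09, 0.0566) had 0 members passed. The macrophage list passed camera without control CD172a+ replicate 1 (0.00938) or 2 (0.0172), the ribosomal list without either of these or CD24+ replicate 2 (0.00371 to 0.0496), and neutrophil markers without control CD172a+ replicate 2 (0.0485) or 3 (0.0396). The macrophage and ribosomal lists passed with the array set as a block (0.000803 and 0.0075), but with that block adjusted p = 0.289 and 0.456 with an estimated correlation. Between CD172a+ cDCs labelled Zeb2-deficient and controls, chemokines and receptors (median 0.03, mean -0.04), erythroid and platelet markers (0.01 and -0.02) and Notch genes (both 0.01, camera pointing down) did not have 1 sign in all measures. Between CD24+ and CD172a+ cDCs, medians had opposite signs in the first and second array sets for DC maturation (-0.35 and 0.11), MHC class II (-0.18 and 0.12), NK cell markers (0.02 and -0.12), Notch genes (0.03 and -0.08), chemokines and receptors (0.03 and -0.10) and epithelial genes (0.04 and -0.02).

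Genes outside the naming rule, chosen after their values were seen, passed between labelled Zeb2-deficient and control CD172a+ cDCs with the array set as a block and not with group as the only factor. Cdh17, an intestinal cadherin, read 7.66 ± 0.52 against 6.17 ± 0.34 (2.80-fold higher, adjusted p = 0.0197 with the block and 0.214 without), and Cysltr1, a leukotriene receptor, 7.47 ± 0.14 against 6.28 ± 0.47 (0.0203 and 0.731). Cd81, a tetraspanin, read 8.45 ± 0.33 against 9.22 ± 0.26 (0.0304 and 0.622), Pla2g7, which degrades platelet-activating factor, 7.55 ± 0.36 against 8.20 ± 0.19 (0.013 and 0.785), and Cd300ld, a receptor of myeloid cells, 7.38 ± 0.64 against 8.26 ± 0.57 (0.00275 and 0.998, and 0.0273 with the replicate number as a block on 8 arrays). The difference between the groups differed between the array sets for 1 gene in limma (1378 at an unadjusted p below 0.05). Across all genes, the differences within the 2 sets correlated only at r = 0.195.

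Other splits of the same arrays show what chance could exclude. For labelled Zeb2-deficient against control CD172a+ cDCs, 2 of 35 splits of the 8 arrays gave at least the 10 genes of the real one, so that chance was not excluded by this count. The other split, with 4314 genes, parts the arrays by array set and points to a structure of the samples, and among the 8 splits that part all 4 replicate numbers the others gave at most 0 genes. With the array set as a block the real split gave 29 genes and the highest other 0, but 18 splits, of which 1 reached 29, are too few for a share under 0.05. For CD24+ against CD172a+ cDCs, 1 of 35 splits gave as many as the real 1278 genes and the highest other 1, and for labelled Zeb2-deficient CD172a+ against CD24+ cDCs, 1 of 35 gave 1429 and the highest other 1, so that chance could be excluded for both.

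Fcer2a, Ms4a1 and Cox6a2, genes known from B cells and pDCs, were higher in CD172a+ cDCs labelled Zeb2-deficient, in every array of the group. Over all genes, Ms4a1 did not pass with group as the only factor. B cells in the sorted cells would raise the other B cell markers too, but the median difference of the other 12 was 0.0614 (95% bootstrap interval -0.083 to 0.168), below the bound of 0.505, with 0.203 (-0.097 to 0.363, bound 0.482) in the first array set and -0.0319 (-0.197 to 0.0545, bound 0.504) in the second. Cd79a and Cd79b, abundant in B cells, read 3.31 and 7.23 in controls and 3.38 and 7.10 in the arrays labelled Zeb2-deficient, while Fcrla and Blk differed by 0.41 and 0.46, and 0 of 14 members belong to another list and 6 lie above the median level in control CD172a+ cDCs. Plasmacytoid DCs would raise the other pDC markers, whose median over 21 genes was 0.0669 (-0.0722 to 0.236), below the bound of 0.523. It was 0.117 (0.0229 to 0.241, bound 0.597) in the first array set, an interval above 0, and 0.0218 (-0.0843 to 0.135, bound 0.449) in the second. Siglech read 5.67 in controls and 6.10 in the arrays labelled Zeb2-deficient, and Bst2 read 8.17 and 8.36. In the second array set Siglech read 5.030 and 5.525 in controls and 6.103 and 6.272 in the arrays labelled Zeb2-deficient. In the first set it read 6.431 and 5.686 in controls and 6.040 and 5.992 in the arrays labelled Zeb2-deficient. Of the 22 pDC markers, 8 belong to another list and 14 lie above that median level. The medians of the other markers thus argue against either cell type as the source of rises of this size. A small share of pDCs is not excluded in either array set, given the interval above 0 in the first and Siglech in the second. A change of these genes within CD172a+ cDCs may be a candidate explanation, a hypothesis found and tested on the same data. For such a change, loss of Zeb2 and the CD11c-Cre transgene cannot be told apart.

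Lyz2 and Csf1r were lower in CD172a+ cDCs labelled Zeb2-deficient, and so was the list of monocyte markers. Fewer monocytes in the sorted cells would lower other monocyte markers, and the median difference of the other 24 was -0.0937 (95% bootstrap interval -0.204 to 0.0388), above the bound of -0.235 set in advance. That bound was wrong to use over all members, since markers near background cannot fall, and over the 18 markers above the median level of 5.52 the median was -0.167 (-0.412 to -0.0504), whose interval crosses the bound. Of the 26 markers, 6 belong to another list and 20 lie above that level in control CD172a+ cDCs, and of members with high levels, chosen after their values were seen, Plac8 differed by 0.37 and Ms4a6c by -0.06. Fewer monocytes and a change within CD172a+ cDCs therefore cannot be told apart for Lyz2 and Csf1r, since a sort for CD172a does not by itself remove monocytes.

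The 2 array sets were found from the same values in which 5998 genes differed between them, so that this count tests nothing. Vcam1 (2.14), Spic (1.86) and C1qc (2.62), genes of splenic macrophages, and Cd14 (3.19), a coreceptor for lipopolysaccharide, were higher in the second set, and the immediate-early gene Fos (-2.51) and the heat-shock genes Hspa1a (-2.78) and Dnajb1 (-2.24) lower. Normalization between arrays stays open. The first component of within-group deviations held 62.1% of the variance as deposited and 61% after quantile normalization. RMA had already applied quantile normalization, so a second round could hardly change this share and cannot decide the question. An uneven mix of CD24+ and CD172a+ cDCs in the control CD172a+ arrays is argued against as the main source of the set difference. The set difference there had a squared correlation of 2.2e-05 with the CD24+ against CD172a+ difference, below the bound of 0.25 (0.00112 in the other version of the test). That test runs over all genes and cannot exclude a small share of CD24+ cDCs. The mean of cDC1 markers was 6.16 and 6.19 in control CD172a+ arrays of the first set and 6.42 and 6.51 in the second. Over all arrays, 7 of their 27 measured members were higher and 6 lower in the second set. The test also cannot see an uneven mix of cells within CD172a+ cDCs, which was not tested. A batch shared by all groups stays open, since the correlation of the set differences between groups, at least 0.616, is partly built into how the sets were found, and no label names a batch. The order of the deposited samples does not come from the values, and it parts the arrays in the same way. The first 5 samples are the first set and the other 6 the second, each with arrays of every group. This order goes with a shared batch but does not by itself show one. A differing share of macrophages was not tested, and neither was any other biological explanation beyond the mix of CD24+ and CD172a+ cDCs.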
